A study of Mus musculus with 6 samples.

How the data were processed

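The series holds 6 libraries of cortex at postnatal day 14, in 3 groups of 2 by their titles: AGO2-bound miRNA, AGO2-bound target and input. Per the labels' protocols, RNA bound to Spy3-AGO2 was isolated on a resin carrying SpyCatcher3, size-selected on a gel between 70 and 150 kDa, ligated to adapters with random bases on both ends, amplified and sequenced as 100 bp single reads. The submitters' processing notes name UMI-tools, cutadapt 2.10, STAR 2.5.2a, Bowtie2 2.4.2, DESeq2 1.36.0, deepTools 3.1.3 and the mm10 build, with no role or order; which tool made which file, and the peak caller and its settings, are not given in the sources used here. The miRNA values are counts as deposited, whole numbers per mature miRNA that the authors did not normalize. The name given to these counts says that duplicate reads were not removed, so 1 molecule can give several counts. Intervals and limits, and the chi-square and binomial tests between the miRNA libraries, cover read counting error only. A row for unassigned reads held 0 counts in both libraries and was left out.

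The peaks are 1 deposited list for the series, with position, name and strand. The score that the authors' list carries is 0 for every one of the 2197 peaks, so it ranks nothing. The sources used here do not say whether peaks were called on pooled target libraries or against the input. With no per-library values, peaks have no replicate check. Coordinates are printed counting from 1.

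Genes were taken from a table of gene spans on GRCm38.p6, the assembly that mm10 holds, which gives no strand, exons or sequence. A peak was credited to every gene whose span held its midpoint, except that peaks in small noncoding RNA genes were not credited to their host genes. Of the peaks, 1726 lay in 1 span, 219 in several and 252 in none; 2 of the last lie in the mitochondrial genome and are counted there. All 375 genes of the gene lists matched the table. Because no genome sequence or transcript models were used here, the planned tests of seed sites, of site position, of 7-mers and of abundance against seed enrichment were not run. The planned 3′ untranslated region share was replaced by the share in the last 10% of the gene span, and matching on untranslated region length by matching on span in 10 classes of equal size.

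Each miRNA's share is its count over the library total, given as mean and SD over the 2 libraries. With 1 group of counts there is no test between groups. Library-scaled counts (CPM) entered correlations as log2(CPM + 1), over miRNAs with at least 10 counts summed. Shares of peaks and genes have exact (Clopper-Pearson) 95% intervals. Position was tested against 1000 uniform placements of each peak along its gene span, and gene lists against 10000 random lists of protein-coding genes, both two-sided permutation tests. Their smallest p is 0.002 and 0.0002. Benjamini-Hochberg adjustment was over the 16 gene lists, with a threshold of 0.05. Where lists of gene function were compared with one another, it was over those 10 lists. The binomial test between the miRNA libraries, the comparison of lists of gene function with one another and the sum over the chromosome 12 locus were not part of the plan. The miRNA lists (11), gene lists (16), seed families (120, covering 88.6% and 88.4% of the counts) and target pairs were fixed before the data were examined, from general knowledge.

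The text names the 15 most abundant miRNAs, up to 3 per miRNA list, the 20 most abundant families, the 10 genes with the most peaks, up to 4 per gene list and the target pairs with a peak in the gene; the planned rule asked for a site in that peak, which was not tested. Some genes that this rule names are not reported here. Names outside this rule were chosen after their values were seen. Alternatives were leaving out each library, the denominator without miR-128-3p, edgeR's TMM factors (0.988 and 1.01) and DESeq2 size factors (0.943 and 1.06), other count minimums and pseudocounts, other rules for peak position, at least 2 peaks per gene, and random lists without matching.

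The binomial test, the gene list test and the placement test along gene spans were checked on simulated data; the chi-square, Fisher and mitochondrial placement tests were not. For the binomial test between the miRNA libraries, with the shares of all other miRNAs kept, 16 of 20 miRNAs changed 4-fold and 11 of 20 changed 2-fold were called, and 0 of 260 unchanged ones. With all changes upward, 41 of 262 miRNAs that were not changed themselves were called, because a share falls when others rise. For the gene lists, with simulated peaks on protein-coding genes drawn at random, 20 of 20 planted lists and 0 of 300 others were called. That setting leaves out expression, so it does not show how often lists of highly expressed genes pass for that reason. It also leaves out span, on which the real peaks depend. Peaks were planted in a larger share of members than had one in most lists that passed, so detection at lower shares was not checked. For placement, 9 of 200 uniform sets of 1569 peaks gave p under 0.05, and with peaks moved so that 37% lay in the last 10% of the span, 38.2% was found. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.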

Results

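RNA bound to a tagged Argonaute protein was measured in cortex of mice at postnatal day 14. The mice carried a conditional Spy3-AGO2 allele, in which AGO2, the protein that holds a microRNA (miRNA) and its target RNA, bears a peptide tag that couples to the SpyCatcher3 protein on a resin. A VGLUT2-Cre driver switched the tag on, and the labels name pyramidal neurons, the excitatory projection neurons of the cortex, as the cell type. The 6 libraries of the series fall into 3 groups of 2: AGO2-bound miRNA libraries, AGO2-bound target libraries and input libraries from whole lysate. Per-library values were used here for the miRNA group only, as read counts per mature miRNA. The target side was used as 1 list of 2197 peaks for the whole series, and no values of single target or input libraries were analysed here. The 2 miRNA libraries held 66854 and 75658 counts over 1978 listed miRNAs, of which 471 and 495 had at least 1 count and 412 had a count in both. A count of 0 allowed a share of up to 0.00449% in replicate 1 and 0.00397% in replicate 2. The labels do not say whether the replicates came from separate animals, so their spread may be technical.

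The first question was which miRNAs AGO2 held in these neurons. miR-128-3p, a brain miRNA abundant in neurons, took 13.2% ± 0.305 (SD, n = 2) of all counts. It was followed by miR-125b-5p with 6.43% ± 0.332, miR-9-5p with 6.42% ± 0.273 and miR-124-3p, the miRNA most closely tied to neuronal identity, with 5.57% ± 0.0830 (SD, n = 2 each). These 4 miRNAs together made up 31.7% ± 0.217 of the counts (SD, n = 2). The order of miR-125b-5p and miR-9-5p was not resolved, since the gap between their means was smaller than either SD. The gap between miR-128-3p and the next miRNA was many times the spread of both.

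miR-136-5p, from the imprinted Dlk1-Dio3 region of chromosome 12, ranked next with 2.76% ± 0.00377 (SD, n = 2), ahead of miR-26a-5p with 2.53% ± 0.0423. The other members of the 15 most abundant were let-7c-5p (2.34%), miR-125a-5p (2.05%), miR-29a-3p (2.02%), let-7a-5p (1.69%), let-7f-5p (1.56%), miR-132-3p (1.47%), miR-29c-3p (1.37%), miR-376a-3p (1.37%) and let-7b-5p (1.11%), each as a mean share of counts. miR-132-3p is known as an activity-regulated miRNA of neurons. All 15 together held 51.9% ± 0.387 of the counts (SD, n = 2). On mm10, miR-136-5p lies in Mir136 (chromosome 12, 109595327 to 109595388), miR-132-3p in Mir132 (chromosome 11, 75173682 to 75173747) and miR-376a-3p in Mir376a (chromosome 12, 109723781 to 109723848). miR-128-3p is the product of Mir128-1 (chromosome 1, 128202361 to 128202430) and Mir128-2 (chromosome 9, 112118636 to 112118711), whose contributions a count of the mature form does not separate.

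**Figure D1:**
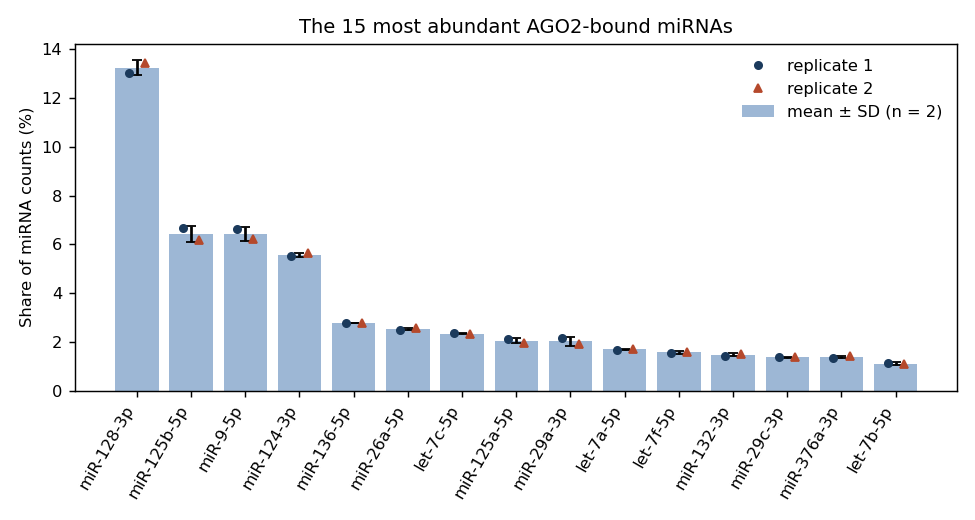
Share of miRNA counts in percent (vertical axis) for the 15 most abundant AGO2-bound miRNAs (horizontal axis). Bars give the mean of the 2 libraries, error bars the SD, and points the single libraries; miR-128-3p stands at 13.2% and the next at 6.43%.

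Grouped by seed family, the set of miRNAs that share the bases pairing with a target, miR-128-3p stayed first with 13.2%. The let-7 family held 10.03% ± 0.215, the miR-125 family 8.48% ± 0.448, miR-9-5p 6.42% and miR-124-3p 5.57% of the counts (SD, n = 2). These 5 families together held 43.7% ± 0.548. The miR-29 family followed with 4.42% ± 0.366 and the miR-30 family with 3.78% ± 0.167 (SD, n = 2). Families 8 to 20 were miR-136-5p (2.76%), miR-26 (2.65%), miR-181 (1.90%), the miR-132 and miR-212 family (1.56%), miR-135 (1.46%), miR-15/16 (1.39%), miR-376a-3p (1.37%), miR-22-3p (1.09%), miR-487b-3p (1.00%), miR-9-3p (0.976%), miR-138-5p (0.941%), miR-434-3p (0.925%) and miR-139-5p (0.871%). The 20 families held 70.8% of the counts. Family membership was written from general knowledge and was not checked against sequence.

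Counts were then summed over lists of marker miRNAs fixed before the data were examined. The neuron-enriched list held 32.4% ± 0.444 of the counts (SD, n = 2), led by miR-128-3p, miR-9-5p and miR-124-3p. The imprinted Dlk1-Dio3 cluster held 14.2% ± 0.0994, with 40 of its 41 listed members counted in both libraries, led by miR-136-5p, miR-376a-3p and miR-487b-3p (1.00%). The let-7 list, made up of miRNAs that rise as cells mature, held 10.03% ± 0.215, while the miR-17-92 cluster and its paralogs, linked to proliferation, held 0.549% ± 0.000626, led by miR-106b-5p (0.134%), miR-19b-3p (0.122%) and miR-93-5p (0.0867%).

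Most lists of markers of other cell types held far lower shares. The lists differ in size and in members, and no miRNA counts of whole lysate were used here. The shares therefore do not measure how far the pull-down was limited to neurons. The oligodendrocyte-enriched list held 0.0755% ± 0.00730 (SD, n = 2), with miR-338-5p at 0.0330% (22 counts in replicate 1 and 25 in replicate 2), miR-219a-5p at 0.0225% (16 and 16 counts) and miR-338-3p at 0.0178% (7 and 19 counts). The endothelial and mural list held 0.149% ± 0.00308, most of it miR-126a-3p (0.130%, 87 and 99 counts), an endothelial miRNA, with miR-143-3p at 0.0113% (8 and 8 counts) and miR-145a-5p at 0.00365% (4 and 1 counts). The microglia and haematopoietic list held 0.174% ± 0.0662, most of it miR-21a-5p (0.148%, 71 and 143 counts), a miRNA found in many cell types, with miR-146a-5p at 0.0122% (4 and 14 counts) and miR-150-5p at 0.00779% (6 and 5 counts). The erythroid list held 0.0134% ± 0.00217, from miR-451a (0.0114%, 9 and 7 counts) and miR-144-3p (0.00207%, 1 and 2 counts). The control lists of epithelial miRNAs and of liver and muscle miRNAs held 0.0495% ± 0.00659 and 0.0372% ± 0.000273, led in the epithelial list by miR-200a-3p (0.0181%, 11 and 15 counts) and miR-200b-3p (0.0166%, 8 and 16 counts). A list of miRNAs enriched in cultured astrocytes held 4.60% ± 0.30, nearly all of it from miR-29a-3p, miR-29c-3p and miR-29b-3p (1.03%), which neurons also express, so its share does not separate the cell types.

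**Figure D2:**
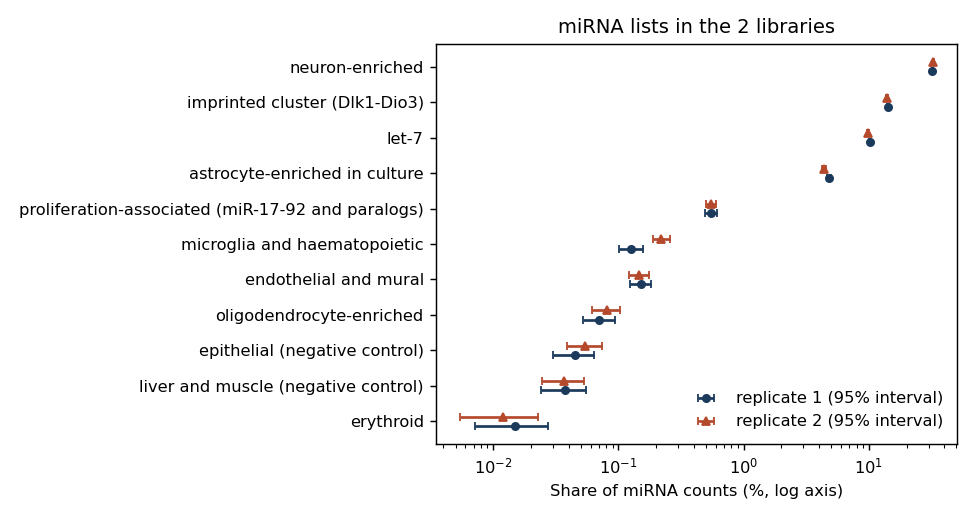
Share of miRNA counts in percent (horizontal log axis) for each list of marker miRNAs (vertical axis), with 1 point per library and its exact 95% binomial interval. The neuron-enriched list stands at 32.4%, and the oligodendrocyte-enriched list at 0.0755%.

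The 2 miRNA libraries were close but not copies of one another. Over the 310 miRNAs with at least 10 counts summed, log2(CPM + 1) correlated with Pearson r = 0.967 and Spearman rho = 0.967 across miRNAs, which are not independent replicates, and the log2 ratio had an SD of 0.60. Counts differed by more than sampling noise (chi-square 598 on 309 degrees of freedom), a comparison with read counting noise alone, which duplicate reads also exceed. Both libraries were kept as replicates because the labels name them so. Of the 15 most abundant miRNAs in each library, 14 were shared. An exact binomial test of each miRNA between the libraries, which compares these libraries and not conditions and whose p-values are too small where reads are duplicates, called 4 of the 310 after Benjamini-Hochberg adjustment, with 46 at an unadjusted p under 0.05. miR-29b-3p was higher in replicate 1 (1.16% against 0.912% of the counts, exact adjusted p = 0.00159), and miR-125b-5p was higher there too (6.67% against 6.20% of the counts, exact adjusted p = 0.0391). miR-376a-5p (54 and 122 counts, exact adjusted p = 0.00223) and miR-21a-5p (71 and 143 counts, exact adjusted p = 0.00513) were higher in replicate 2.

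The second question was where the AGO2 target peaks lay. Whether they were called against the input is not known here, so a peak does not by itself show AGO2 binding. The 2197 deposited peaks, 1206 on the plus and 991 on the minus strand of mm10, were 15 to 407 nt wide with a median of 53 nt and covered 139956 bases. Protein-coding gene spans held 1624 of them (73.9%, exact 95% interval 72.0 to 75.7). Small noncoding RNA genes held 108 (4.92%), of which 79 lay in snoRNA genes, lncRNA genes held 103 (4.69%), and the mitochondrial genome held 103 (4.69%). A further 250 peaks (11.4%) lay in no annotated gene span, and 9 in pseudogenes or other genes. Peaks fell in 941 nuclear protein-coding genes, 643 of them with 1 peak and 64 with at least 5. Gene spans carry no strand in the table used, so a peak antisense to a gene was not told apart from a sense peak.

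Slc1a2, the glutamate transporter that is most abundant in astrocytes and also present in some axon terminals, had the most peaks, 45, all on the plus strand. Its span lies on chromosome 2 (102658239 to 102790784), and 40 of its peaks lay in the last 10 kb, between 102781471 and 102790761, where they covered 26.0% of the bases. Malat1, a nuclear lncRNA (chromosome 19, 5795690 to 5802672), had 38 peaks. The imprinted lncRNA Meg3 (chromosome 12, 109540996 to 109571729) had 19, of which 8 also lay in an overlapping gene. Gpm6a, a neuronal membrane glycoprotein gene (chromosome 8, 54779434 to 55060878), and Atp2a2, the calcium pump of the endoplasmic reticulum (chromosome 5, 122453513 to 122502225), had 14 each. Syt1, the calcium sensor of transmitter release (chromosome 10, 108497650 to 109010980), and the lncRNA gene Gm36601 had 14 each, of which 13 were the same peaks because the spans overlap. Mitochondrial genes among the 10 genes with the most peaks were ND5 with 17 and mt-Rnr2 with 16.

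Peaks gathered at the 3′ ends of genes. Of 1569 peaks in 849 protein-coding genes, 66.0% (exact 95% interval 63.6 to 68.4) had their midpoint in the last 10% of the gene span, read along the strand of the peak. Random placement along the same spans gave 9.99%, with 12.5% as the highest of 1000 placements (two-sided permutation p = 0.002, the smallest these placements can give). The share was 66.6% for plus-strand and 65.4% for minus-strand peaks, and 2.49% of peaks lay in the first 10%. The median peak lay 1.63 kb from the end of its span. The interval and the placements treat peaks of the same gene as independent. Counted by gene, 58.8% of the 849 genes had their median peak position in the last 10%, below that interval. This share by gene was not set against random placement. Spans include introns and were used in place of exons and untranslated regions, so these shares are not shares of 3′ untranslated regions, and spliced transcripts place more of their length near the end of a span than uniform placement does.

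**Figure D3:**
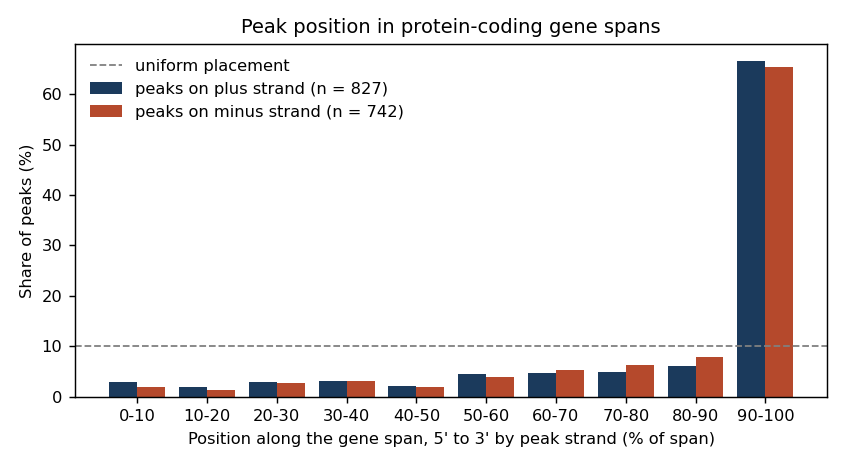
Share of peaks in percent (vertical axis) by position along the protein-coding gene span in steps of 10% (horizontal axis), for 827 plus-strand and 742 minus-strand peaks. The dashed line marks uniform placement; the last 10% of the span held 66.6% and 65.4% of the peaks.

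Synaptic and cytoskeletal genes carried peaks more often than random protein-coding genes of the same span. Among 16 gene lists fixed before the data were examined, 19 of 31 presynaptic genes (61.3%) had at least 1 peak, against 2.68 in random lists matched on span, as had 19 of 37 postsynaptic genes (51.4%, 3.84 in random lists) and 18 of 28 neuronal cytoskeleton genes (64.3%, 2.28 in random lists). The adjusted permutation p was 0.00107 for each of the 3 after Benjamini-Hochberg adjustment over the 16 lists, from a raw p of 0.0002, the smallest that 10000 random lists can give. Presynaptic genes with the most peaks were Syt1 (14), Snap25 (8), a SNARE protein of the plasma membrane, Vamp2 (7), its partner on the vesicle, and Bsn (6), an active zone scaffold. Postsynaptic genes with the most peaks included the NMDA receptor gene Grin2b (7), the GABA receptor gene Gabrb2 (5) and the scaffold gene Shank1 (5). Cytoskeletal genes were led by Ank2, Dclk1 and Map1b with 7 peaks each and Dpysl2 with 6. The random lists were not matched on expression, which was not measured here, so a list of highly expressed genes can pass for that reason alone.

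Regulators of expression and signalling also passed. Genes of PI3K, mTOR and MAPK signalling had peaks in 9 of 25 (36.0%, adjusted permutation p = 0.00240), among them Gsk3b (4), Nf1 (2) and Pik3r1 (2). Transcription and chromatin genes had peaks in 10 of 30 (33.3%, adjusted permutation p = 0.00320), led by the activity-dependent transcription factor gene Mef2c (9) and by Tcf4 (3), with Arid1a and Bcl11a at 1 each. RNA-binding proteins had peaks in 9 of 28 (32.1%, adjusted permutation p = 0.00533), among them Pum2 (5), Celf4 (3) and Msi2 (2), and ion channels in 9 of 28 (adjusted permutation p = 0.0114), led by the sodium channel gene Scn2a (6), with Cacna2d1 and Kcna2 at 2 and Cacnb4 at 1. With at least 2 peaks required per gene, transcription and chromatin (adjusted permutation p = 0.756) and ion channels (0.307) no longer passed. Axon guidance and adhesion genes had peaks in 7 of 34 (adjusted permutation p = 0.279), with Cntn1 and Epha4 at 2 and L1cam and Ncam1 at 1. Genes of ubiquitin and protein turnover had peaks in 4 of 20 (adjusted permutation p = 0.209), Fbxo45, Trim9, Ube2g1 and Usp22, each with 1. Neither list passed, though both did against random lists not matched on span (0.00284 and 0.0301). Genes of the miRNA pathway had a peak in 1 of 22, the RNA helicase gene Ddx6 (2 peaks, adjusted permutation p = 0.965). Set against the genes of the other lists of gene function, their share was lower (4.55% against 39.8%, Fisher's exact adjusted p = 0.00428 over 10 lists). This comparison was unplanned and not matched on span or expression, and most of the other genes came from lists that passed. Against random lists matched on span their count was not detectably low (1 against 1.68). In the same comparison presynaptic and cytoskeleton genes had higher shares than the rest (Fisher's exact adjusted p = 0.0171 and 0.0160).

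**Figure D4:**
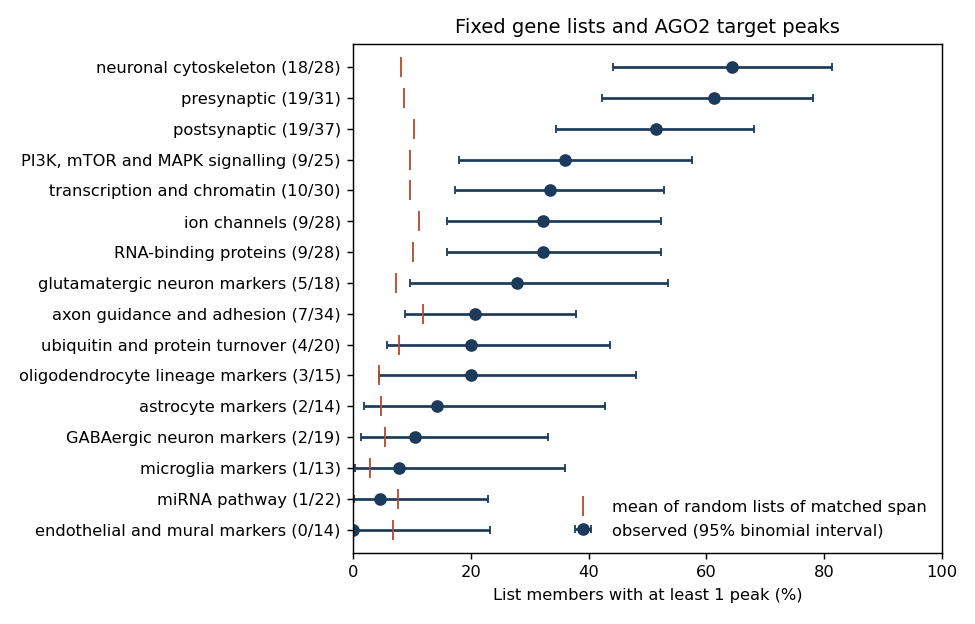
Percent of list members with at least 1 peak (horizontal axis) for the 16 gene lists (vertical axis, with members with a peak over members), with exact 95% binomial intervals. Ticks mark the mean of 10000 random lists of matched span; neuronal cytoskeleton genes stand at 64.3% and miRNA pathway genes at 4.55%.

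Among cell type markers, 5 of 18 glutamatergic neuron markers had a peak (27.8%, adjusted permutation p = 0.0220), among them the vesicular glutamate transporter gene Slc17a7 (5), Camk2a (4) and Nrgn (1). GABAergic neuron markers had a peak in 2 of 19 (adjusted permutation p = 0.685), among them Sst with 1. Astrocyte markers had one in 2 of 14 (0.372), among them Slc1a2 with 45, and oligodendrocyte lineage markers in 3 of 15 (0.0867), among them the myelin genes Mbp with 2 and Cnp with 1. Microglia markers had one in 1 of 13 (0.706), Siglech, and endothelial and mural markers in 0 of 14 (0.781). Set against the pooled glial and vascular markers, of which 6 of 56 had a peak (10.7%), no difference was detectable with lists of this size (Fisher's exact test, two-sided, odds ratio 3.21, p = 0.122). Counting only peaks in the last 10% of the span gave 5 of 18 against 3 of 56 (Fisher's exact p = 0.0178), a setting chosen after the data were seen. No other setting gave p under 0.05. Fisher's exact p was 0.150 with at least 2 peaks per gene, and 0.0564 both with wide peaks only and with a single gene span.

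The last question was whether the genes of well-known miRNA targets carried peaks. Of 49 pairs of a miRNA family and a target gene, fixed beforehand over 13 families, 9 had a peak in the gene, among them Map1b (7) and Foxp1 (1) for miR-9-5p, Arhgap32 (1) for the miR-132 and miR-212 family, Pum2 (5) for miR-134-5p, Gsk3b (4) for miR-26, Dnmt3a (1) for miR-29, Gria2 (3) for miR-181 and Grin2a (4) for miR-125. Of the 16 pairs of let-7 and miR-124-3p, 0 had one. The 48 genes of these pairs were not compared with other genes, so the 9 with a peak do not show that known targets were bound more often. Whether a peak held a site of its miRNA was not tested, since no genome sequence was used here, so these counts do not assign a peak to a miRNA.

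The mitochondrial genome carried 103 peaks, 94 on the plus strand and 9 on the minus strand. Up to position 16189, the end of the last peak, they covered 40.3% of the sequence at 6.36 peaks per kb. The ribosomal RNA genes held 24 of them. Peaks were missing from 6438 to 9810 and from 9880 to 11018.

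**Figure D5:**
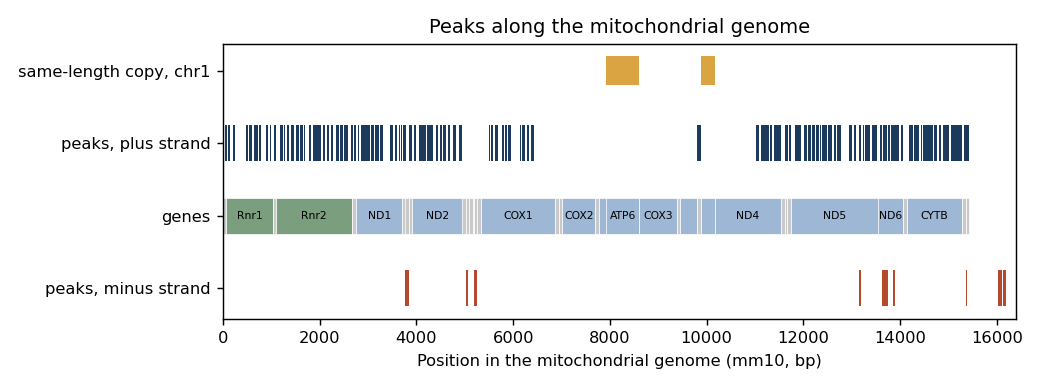
Peaks along the mitochondrial genome (horizontal axis, position in bp on mm10) by strand, with the annotated genes and the mitochondrial positions of 2 genes whose lengths recur in neighbouring pseudogenes on chromosome 1. Peaks are absent from 6438 to 9810.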

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

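The settings with peaks wider than 30 nt, peaks in the last 10% of the span, a single gene span, any overlap for the gene lists, peaks without Slc1a2, and count minimums for the binomial test between the libraries were chosen after the data were seen. Leaving out 1 of 2 libraries cannot move a share by more than the SD, so it says nothing of stability. TMM and DESeq2 size factors moved no named miRNA by more than its SD. Both sets of factors lay close to scaling by library total, so they could hardly move a mean share, and this too says nothing of stability. With miR-128-3p taken out of the denominator and of the sets that hold it, the 15 most abundant miRNAs stood lower, at 44.6%, as did the neuron-enriched list, at 22.0%. The other lists rose by construction, among them to 16.3% (Dlk1-Dio3), 11.6% (let-7), 5.30% (cultured astrocytes), 0.633% (miR-17-92), 0.172% (endothelial and mural), 0.0870% (oligodendrocyte), 0.0571% (epithelial) and 0.0429% (liver and muscle). Pearson r between the libraries was 0.802 with no count minimum, where low counts dominate, and 0.988 at 100 counts.

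The 3′ position held under every alternative, at 65.3% to 76.8% of peaks. Between 6 and 10 gene lists passed, against 8. With at least 2 peaks per gene, ion channels (3 genes) and transcription and chromatin (2) no longer passed, and microglia (0), ubiquitin (0) and miRNA pathway genes (1) changed sides of the random mean without passing on either. Against unmatched lists axon guidance (7) and ubiquitin (4) passed, and the miRNA pathway (1) lay above the mean. With wide peaks only, oligodendrocyte markers passed (3 genes, adjusted permutation p = 0.0448), and microglia markers fell to 0, as with peaks in the last 10% of the span. There the glutamatergic to glial odds ratio was 6.79. The cause was not tested. No paired analysis was possible because only the miRNA group has values per library. Not run: the upper part of the peaks by score (all are 0) and every alternative on seed sites, 7-mers and 3′ untranslated regions.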

Other observations

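All tests below were chosen after the data were seen. For the position of narrow peaks in gene spans and past gene ends, bounds were written before those values were computed. Narrow peaks had by then been seen to lie outside gene spans.

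The imprinted locus on chromosome 12 between Meg3 and Mirg (109540996 to 109749458) supplied 16.4% ± 0.0426 of the AGO2-bound miRNA counts (SD, n = 2), from 87 mature miRNAs with a single gene there. Its leading members were miR-136-5p (2.76%), miR-376a-3p (1.37%), miR-487b-3p (1.00%), miR-434-3p (0.925%) and miR-127-3p (0.849%). The lncRNA Meg3, whose span ends before the genes of these 5, was among the genes with the most peaks. miRNAs with a single gene on the X chromosome held 1.78% ± 0.0287.

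Most hairpins that could be paired by name gave AGO2 mainly 1 arm. Hairpins such as miR-128, miR-26a and let-7a, whose arms carry different names in the counts, were left out. Of 113 paired hairpins with at least 100 counts over both arms, 84 had more than 90% from 1 arm, 39 of them the 5p and 45 the 3p arm. Another 12 had between 25% and 75% from the 5p arm, such as miR-434 with 39.5% ± 3.05 from 5p (SD, n = 2). Peaks in small noncoding RNA genes lay in snoRNA (79), tRNA (11) and snRNA (8) genes above others, and 3.70% of them had a neighbour within 100 nt on the same strand, against 92.2% of mitochondrial peaks and 94.7% of those in Malat1.

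Narrow peaks of at most 30 nt, 517 of 2197, lay outside every gene span in 36.4% of cases, against 3.69% of wider peaks (Fisher's exact test, two-sided, p = 1.57e-77). Running past annotated gene ends does not account for most of them, since 19.7% (exact 95% interval 14.3 to 26.1) of those outside spans lay within 10 kb past an end along the peak strand, and 22.9% lay as near before a start. Inside protein-coding spans 16.7% (12.5 to 21.5) of narrow peaks lay in the last 10%, above the 9.99% of random placement (two-sided permutation p = 0.004) and far below the 76.8% of wider peaks. Of nuclear narrow peaks, 37.0% (32.8 to 41.4) lay outside spans, while 52.4% of the sequence does. How much of that sequence short reads can be placed in was not measured, so this difference does not exclude random placement as the whole cause. Short fragments placed without regard to transcripts may account for part of the narrow peaks. Whether they account for all was not settled, and no biological explanation was tested.

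Peaks also lay in genes known as astrocyte and oligodendrocyte markers, chiefly Slc1a2, although the tag was driven by VGLUT2-Cre. Of 24 abundant glial genes 14 had a peak, but the list was written after peaks of 13 had been seen, and the bounds of the test were revised after that count; over the other 11 genes 63.6% had one (exact 95% interval 30.8 to 89.1), all 7 astrocyte genes and 0 of 4 oligodendrocyte genes. RNA of other cells carried into the pull-down may contribute, but 7 of the 24 genes, among them Slc1a2 (45 peaks), Sparcl1 (12), Cpe (11) and Gpm6b (8), are known from general knowledge, not checked here, to be expressed by neurons too, while Slc1a3, Aldoc and Gja1 had 0 peaks and Mbp and Cnp had 2 and 1. Oligodendrocyte and microglial miRNAs summed to 0.249% of counts, against 0.0867% for the control lists, but 0.148% was miR-21a-5p, found in many cell types, and the oligodendrocyte list alone (0.0703% and 0.0806% in the 2 libraries) lay below the summed controls (0.0823% and 0.0912%), so neither cell type is shown to have carried the tag, nor excluded; the first bound set for this test, 1% of counts, was replaced by the control lists after the values were seen, and under it the sum would have counted against such cells. These sources cannot be told apart here, because no expression values were used, and no biological explanation was tested.

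Apart from 1 peak at 9811 to 9879, mitochondrial peaks were missing from 6438 in COX1 to 11018 in ND4, and whether reads shared with a nuclear copy of the mitochondrial genome account for this cannot be told. The mitochondrial stretch from 7927 to 10173 spans ATP6 and ND4L, whose lengths of 681 and 297 bp recur in Gm10925 and Gm10222 on chromosome 1, at a distance of 1567 bp there and 1566 bp in the mitochondrial genome. Of 5 pseudogenes on chromosome 1 with the length of a mitochondrial gene, the other 3 lie far from this pair. The stretch held 1 peak, where random placement of the 103 peaks gave 14.3, but 96.9% of it lies in the gaps that raised the question, so its low count was fixed by that choice. Sequence identity was not tested, and no biological explanation was tested.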
